A study of Homo sapiens with 3 samples.

How the data were processed

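The series holds 3 RNA libraries of wild-type MCF-7 cells, 1 per treatment of 24 h: vehicle with 0.1% ethanol, E2 at 1e-09 mol/L and 4-OHT at 1e-06 mol/L. Per the labels' protocols, total RNA was isolated with a column kit, converted to a cDNA library, and sequenced as paired-end reads of 100 bp on an Illumina GAII instrument. The deposited files give 1 FPKM value per gene (fragments per transcript length and sequencing depth), per the file headers, for 36953 Ensembl gene identifiers. The genome build was hg18, per the submitters' processing notes. The aligner, the quantification tool, the annotation release and any filter are not given in the sources used here.

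Each library took its group from the label of the sample its file is attached to. The column header inside each file names another of the 3 treatments. This grouping was kept because it was fixed before the data were examined and because values were not used to assign groups. Using the header names is 1 of the alternatives, and all 3 pairs of libraries are reported, so that either naming can be read from them.

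Identifiers were matched to current gene symbols by Ensembl identifier, with older symbols of list members resolved through RefSeq synonyms; 23779 identifiers (64.3%) had a symbol. Identifiers without a symbol held 18.9%, 17.2% and 21.9% of the summed FPKM in the libraries labelled vehicle, E2 and 4-OHT. Each was kept as a gene of its own in library totals, correlations, counts past 2-fold and the overlap. They also took part in counts of genes listed at 0, except where these are limited to named genes. Gene lists, random lists and genes named in the text left them out. Values of identifiers that share a symbol were summed. Transcript lengths, GC content and gene types came from GENCODE transcripts of a later build, matched by identifier, and no coordinates are given because the files hold none and the available annotation is of another build.

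The depth was estimated from low values. The product of a low value and the longest transcript length clustered at 1, 2 and 3 times a common step within 0.005 on the log10 scale: of 1742 genes with values up to 0.5 FPKM in the library labelled vehicle, 134, 140 and 60 lay at those multiples and 4 at 1.5 steps. The steps put 1 read in a 1-kb gene at 0.186, 0.185 and 0.231 FPKM in the libraries labelled vehicle, E2 and 4-OHT, and the reads in genes at about 58000000, 58400000 and 49800000. The normalising totals that these steps imply were about 5380000, 5420000 and 4320000 reads. By these estimates the values would be about 10.8, 10.8 and 11.5 times those of FPKM computed from the reads in genes. The reads in genes were computed with each gene's longest transcript, which overstates them where shorter transcripts gave the reads. The factors are therefore uncertain and may be too high. Levels should not be compared with FPKM values of other studies. The read counts cover sampling of reads only, and a value of 0 can be a failed estimate.

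Differences were taken on log2(FPKM + 1) between the values as deposited, for 15549 genes, with or without a symbol, with a mean of at least 1 FPKM over the 3 libraries. This scale understates the change of genes near 1 FPKM. A gene was counted as higher or lower when the difference was at least 1 in size, written as 2-fold. With 1 library per group no test and no p-value can be had, so these are rules of size that describe 3 libraries and not the treatments. A total of 26 gene lists was fixed before the data were examined, and each list's median difference was placed among 10000 random lists of the same size matched on mean expression in 10 bins. A list was called apart below the 2.5 or above the 97.5 percentile; lists with under 5 measured members were to be left out, and none was. The lists covered estrogen-induced and estrogen-repressed genes, cell cycle, CDK inhibitors, p53 targets, lipid synthesis, stress responses, the BCL2 family, growth factors, immediate early genes, steroid receptors, markers of luminal, basal, mesenchymal and leukocyte cells, interferon, ribosomes, respiration, lysosome, histones and housekeeping genes.

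Genes named in the text were chosen by a rule fixed before the data were examined: per comparison the 8 with the highest and the 8 with the lowest difference, leaving out most small RNA names, up to 4 members of each list with the largest differences, and always ESR1, PGR, GREB1, TFF1, PDZK1, MYB, CXCL12, CCND1, MYC, MKI67, BCL2, ACTB and GAPDH. EGFR among the basal markers was named outside this rule after its values were seen, as a member that went the other way, and other genes named so are marked. For the overlap of the differences from the shared library, unchanged libraries were simulated 100 times. Their spread came from the median absolute deviation of the differences between the libraries labelled vehicle and E2, within each of 10 bins of mean expression.

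Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, median-ratio and upper-quartile scaling, keeping the highest of identifiers that share a symbol, and thresholds of 1.5-fold and 3-fold. Chosen after seeing the data were the header names, protein-coding genes only, removal of the median trend with GC content in 20 bins, and a filter without the library labelled 4-OHT. The steps were tested on simulated libraries with 200 changed genes. Reads were drawn by sampling alone (Poisson) around the library labelled vehicle, for named genes with a known length. Changed genes were drawn only from those well above the filter in that library. For the libraries labelled E2 and vehicle, with 13469 genes, 101 of 101 genes changed 4-fold and 99 of 99 changed 8-fold passed the 2-fold rule. So did 0.558% of unchanged genes, and 4 of 100 unchanged lists were called apart. These rates hold no variation between cultures or library preparations, so they are not error rates of the real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.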

Results

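Wild-type MCF-7 cells, an estrogen receptor-positive breast cancer cell line, were treated for 24 h with vehicle (0.1% ethanol), with E2 (estradiol, an estrogen) at 1e-09 mol/L, or with 4-OHT (4-hydroxytamoxifen, a selective estrogen receptor modulator) at 1e-06 mol/L. Total RNA was sequenced, and 1 library per treatment gave FPKM values for 36953 Ensembl genes. From the steps between low values, 1 read in a 1-kb gene was worth 0.186 FPKM in the library labelled vehicle, 0.185 in the library labelled E2 and 0.231 in the library labelled 4-OHT. Summed over the genes with a known length, these steps correspond to about 58000000, 58400000 and 49800000 reads. These sums use the longest transcript of each gene, which can overstate the reads. Genes listed at 0 numbered 17885 in the library labelled vehicle, 17839 in the library labelled E2 and 21978 in the library labelled 4-OHT. Across genes on the log2(FPKM + 1) scale, the libraries labelled vehicle and E2 correlated at 0.990, while the library labelled 4-OHT correlated with them at 0.929 and 0.925. With 1 library per treatment, no difference below has a replicate check and none was tested.

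The column header inside each file names a different treatment from the label of the sample it is attached to. The library labelled vehicle is headed 4-OHT, the one labelled E2 is headed vehicle, and the one labelled 4-OHT is headed E2. The 6 estrogen-induced check genes were therefore read before any direction was written, and they went against the labels. All 6 were lowest in the library labelled E2, and 4 of them were highest in the library labelled 4-OHT. GREB1, a coactivator of the estrogen receptor, was at 247 FPKM in the library labelled vehicle, 37.9 in that labelled E2 and 1439 in that labelled 4-OHT. PGR, the progesterone receptor gene, was at 26.1, 0.185 and 300.0 FPKM in the same order, and TFF1, a secreted trefoil peptide gene, at 3309, 1020.4 and 55769.7 FPKM. CXCL12, a chemokine gene, followed that order of libraries at 14.2, 6.40 and 35.0 FPKM. MYB, a transcription factor gene, and PDZK1, a scaffold protein gene, were highest in the library labelled vehicle, at 54.8 and 2.22 FPKM, against 8.18 and 0.264 in that labelled E2 and 35.7 and 0.992 in that labelled 4-OHT. Libraries are named by their labels throughout, every direction is a direction between libraries so labelled, and the headers would rename the same 3 pairs.

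**Figure D1:**
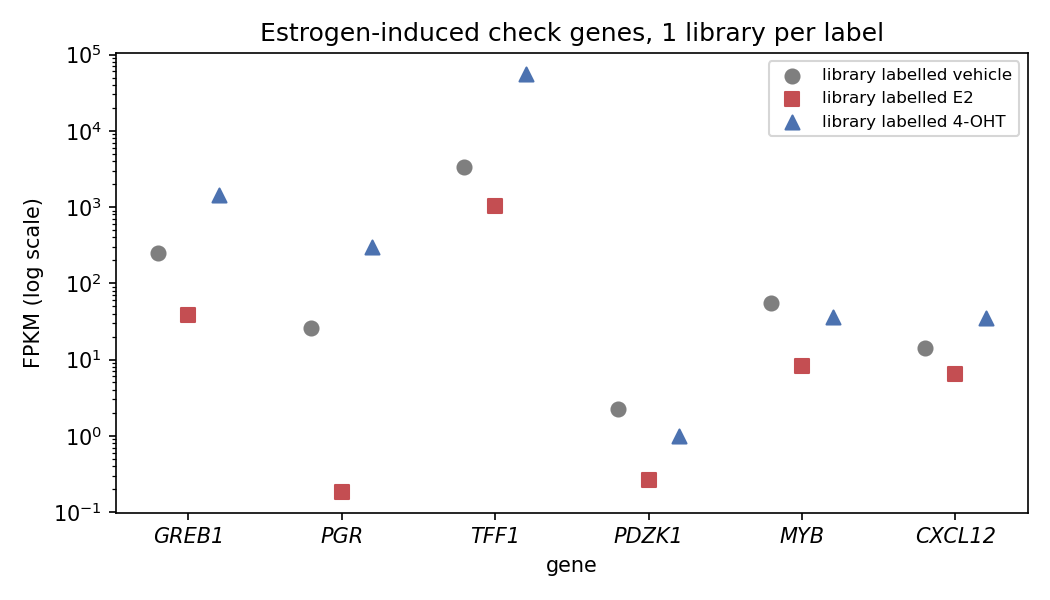
FPKM on a log axis of the 6 estrogen-induced check genes, with 1 point per library (circles, labelled vehicle; squares, labelled E2; triangles, labelled 4-OHT). The square is the lowest point for all 6 genes, and the triangle is the highest for 4 of them.

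The first comparison set the library labelled E2 against the library labelled vehicle, the pair that the labels give for the response to estrogen. Genes known to be induced by estrogen were lower in the library labelled E2: 23 of the 34 measured were at least 2-fold lower and 0 were 2-fold higher, with a list median of -1.28 on the log2(FPKM + 1) scale. PGR stood at 0.185 against 26.1 FPKM, IGFBP4, which encodes a binding protein of insulin-like growth factors, at 462 against 6364, and RAPGEFL1 at 50.7 against 791. Genes known to be repressed by estrogen were higher in the library labelled E2, with a median of 0.64 and 4 of 16 past 2-fold. These 4 were PSCA, a surface antigen gene, at 381 against 58.0 FPKM, the interleukin receptor gene IL1R1 at 72.8 against 13.9, TGFB3 at 583 against 135, and the antiproliferative gene BTG2 at 262 against 121. Among 15549 genes, 401 were at least 2-fold higher and 748 at least 2-fold lower in the library labelled E2, or 7.39% in all. The column headers call this pair vehicle and 4-OHT. The 1149 genes became 485 with a pseudocount of 5, 696 with a mean of at least 5 FPKM and 711 among the 12886 protein-coding genes alone.

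Cell division genes were lower in the library labelled E2. Of 31 mitotic genes, 15 were at least 2-fold lower and 0 higher, with a median of -0.99. TOP2A, the DNA topoisomerase of dividing cells, was at 32.0 against 89.4 FPKM, NUSAP1, a spindle protein gene, at 109.7 against 299, and CDC25C, an activator of mitotic entry, at 12.3 against 29.7. All 30 measured DNA replication genes had their lowest value in the library labelled E2, with a median difference from the library labelled vehicle of -0.63 and 4 members past 2-fold. These were POLE2 (5.68 against 19.0 FPKM), RRM2 (96.8 against 222), RFC3 (22.8 against 51.8) and MCM10 (16.8 against 35.6). The proliferation marker MKI67 was at 134 against 266 FPKM, just short of 2-fold. Cholesterol genes had a median of -0.31 with STARD4, a sterol carrier gene, as the 1 member past 2-fold, at 0.734 against 3.20 FPKM, and the biosynthetic enzyme gene DHCR7 at 1074 against 1780.4. Ribosome biogenesis genes had a median of -0.16 with 0 of 18 past 2-fold.

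Other groups stood higher in the library labelled E2 by small amounts. Luminal epithelial markers had a median of 0.32, with CLDN3, a tight junction gene, at 9692 against 5596 FPKM, yet 2 of its 16 members were at least 2-fold lower. These were AGR2 at 56.4 against 340.1 FPKM and XBP1, a transcription factor of secretory cells, at 969 against 2323. Interferon response genes had a median of 0.26, with IFI6 at 236 against 113 FPKM, and the aryl hydrocarbon receptor and NRF2 targets had 0.24, with the quinone reductase gene NQO1 at 1828 against 845. Basal epithelial markers had 0.27 and p53 targets 0.17. Among the p53 targets, BTG2 was higher and MDM2, the p53 ubiquitin ligase gene, lower past 2-fold, at 56.3 against 126 FPKM. The interferon and aryl hydrocarbon receptor lists fell inside the random range with a pseudocount of 5, the p53 list did so with a pseudocount of 0.1 and with upper-quartile scaling, and the basal list did so in 3 of 9 alternatives.

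Outside these lists, the 8 lowest genes in the library labelled E2 included PGLYRP2, listed at 0 against 223 FPKM, SERPINA1, the alpha-1-antitrypsin gene, at 1.47 against 156, and PTGES, a prostaglandin E synthase gene, at 4.13 against 319. SPINK4 was at 0.597 against 94.9 FPKM, CITED1 at 1.23 against 103, SDK2 at 4.27 against 197, and the kinase gene FGR at 0.0636 against 34.2. The highest were CRYM at 15.3 against 1.14 FPKM, APOBEC3A at 111 against 16.0, PSCA, MC5R at 28.6 against 4.23, SLC16A5 at 7.30 against 0.483 and STRA6 at 11.8 against 1.43, with the small RNA genes RNA5SP194 and RNVU1-21 at 4.90 and 4.89 FPKM and listed at 0 in the library labelled vehicle. The receptor kinase gene RET was at 425 against 2291 FPKM and the AP-1 gene FOSL2 at 151 against 628. MYC was at 45.4 against 104 FPKM. The estrogen receptor gene ESR1 stood at 693 against 608 FPKM, CCND1 at 1445 against 1296, BCL2 at 8.69 against 10.7, ACTB at 19756 against 21409 and GAPDH at 18137 against 18401, none past 2-fold. The remaining 15 lists lay inside the random range: CDK inhibitors, fatty acid synthesis, unfolded protein response, BCL2 family, growth factor, immediate early, steroid receptor, mesenchymal, leukocyte, ribosomal protein, oxidative phosphorylation, lysosome, hypoxia, histone and housekeeping genes. Of these, the CDK inhibitor and growth factor lists left it with a pseudocount of 0.1, the steroid receptor list with the GC trend removed, and the mesenchymal list with either.

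**Figure D2:**
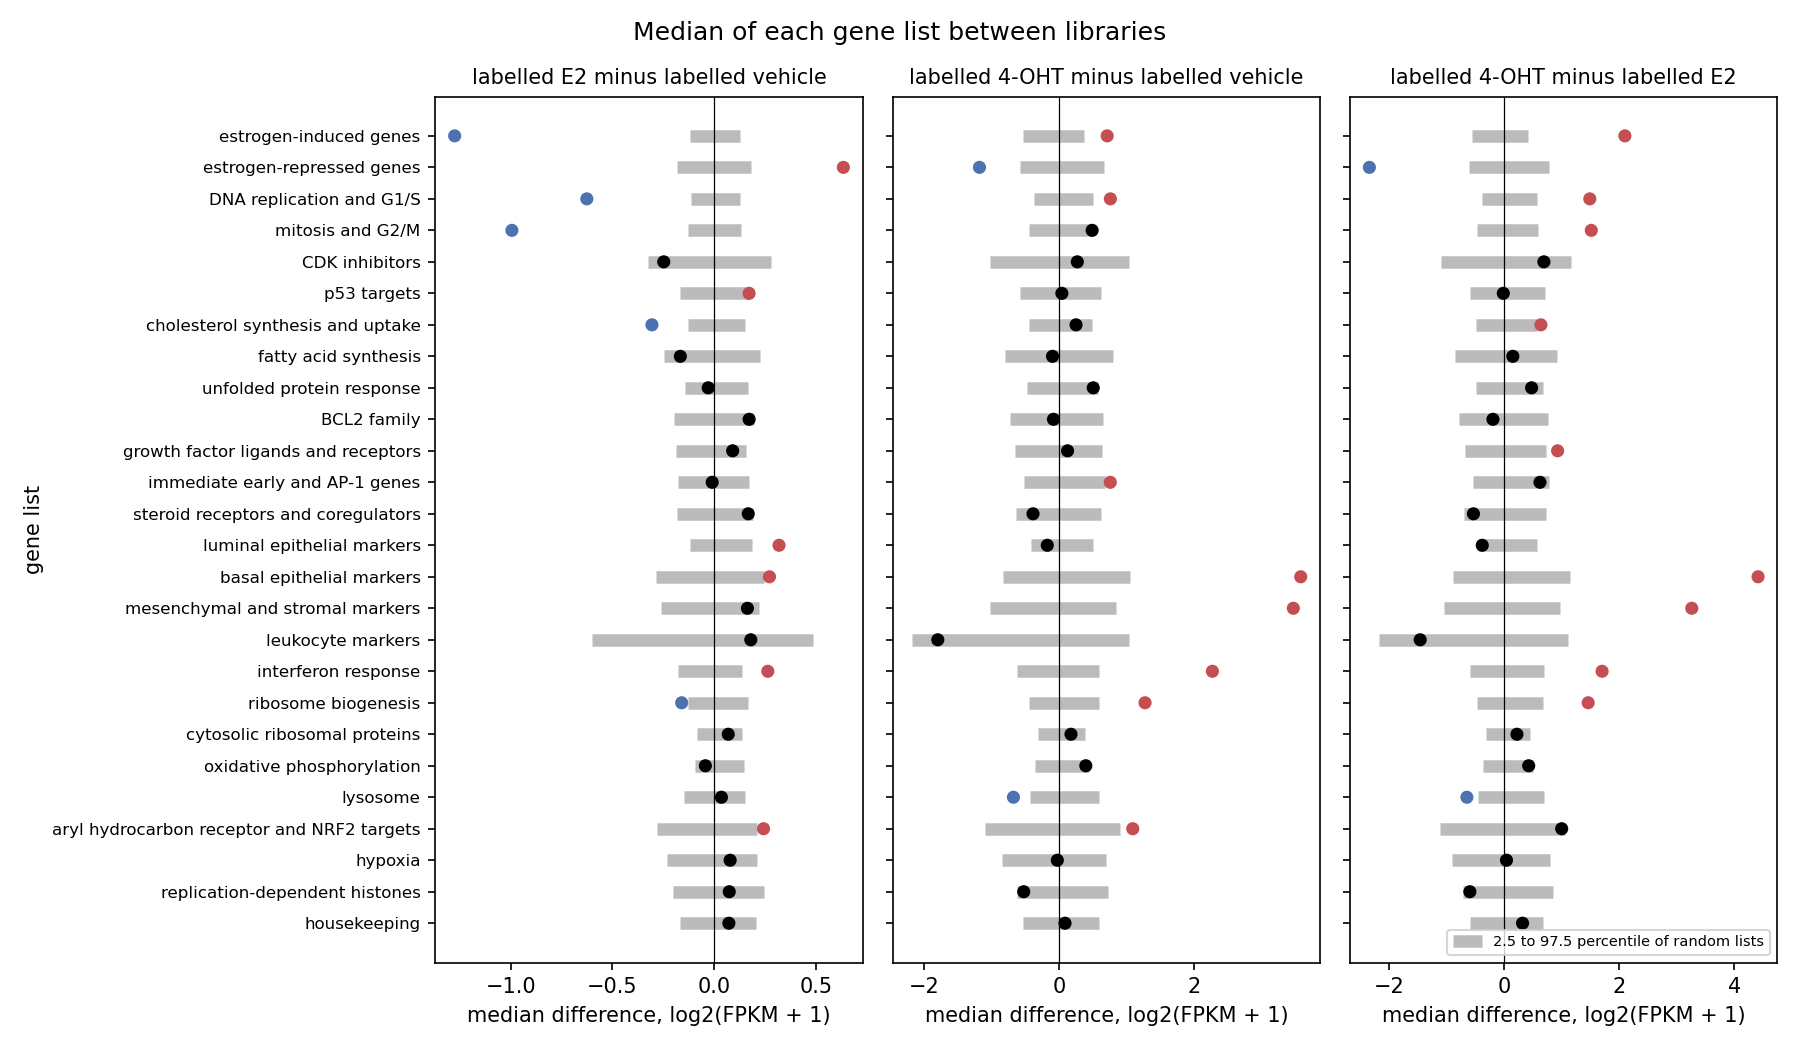
Median difference on the log2(FPKM + 1) scale of each of the 26 gene lists (points) in the 3 comparisons, with the central 95% of 10000 expression-matched random lists (grey bars). Red points lie above that range, blue points below it and black points inside it; 11, 10 and 11 lists lie outside it from left to right.

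The second comparison set the library labelled 4-OHT against the library labelled vehicle, the pair that the labels give for the response to the receptor modulator. Basal epithelial and mesenchymal markers were far higher in the library labelled 4-OHT. The basal keratin genes KRT5 and KRT14 stood at 1060.3 against 3.72 and 391 against 0.455 FPKM, and 7 of 9 basal markers were past 2-fold with a list median of 3.58. VIM, the intermediate filament gene of mesenchymal cells, stood at 3179 against 18.2 FPKM and SPARC, a matrix protein gene, at 489.5 against 2.14, with 8 of 11 mesenchymal markers past 2-fold and a median of 3.47. EGFR, on the basal list, and TWIST1, on the mesenchymal list, were lower past 2-fold, at 26.8 against 65.2 FPKM and listed at 0 against 19.1. Luminal markers were not apart, with a median of -0.18 and 4 of 16 lower past 2-fold: AGR2, CLDN4, ESR1 at 290.3 against 608 FPKM, and CDH1, the E-cadherin gene, at 1197 against 2681. Of 15549 genes, 3051 were at least 2-fold higher and 4812 at least 2-fold lower, or 50.6%, but 2663 and 2948 with a pseudocount of 5. The column headers call this pair E2 and 4-OHT.

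Estrogen-induced genes were higher in the library labelled 4-OHT, with 14 of 34 past 2-fold, 2 lower past 2-fold and a median of 0.71. The zinc finger gene EGR3 was at 235 against 9.26 FPKM, TFF1 at 55769.7 against 3309 and AREG, a ligand of the epidermal growth factor receptor, at 34.3 against 3.30. Estrogen-repressed genes were lower, with 8 of 16 past 2-fold and a median of -1.18. BMF, a proapoptotic gene, was at 4.55 against 146 FPKM, BLNK at 0.249 against 38.7 and TP53INP1 at 0.991 against 30.4. In the same pair of libraries the basal and mesenchymal markers stood as given above.

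Interferon response genes had 18 of 24 members higher past 2-fold and a median of 2.27 in the library labelled 4-OHT, beside the higher basal and mesenchymal markers. IFI27 was at 752 against 3.70 FPKM, IFIT3 at 70.8 against 0.653, and IFI44 at 126 and listed at 0 in both other libraries. Ribosome biogenesis genes had 12 of 18 higher past 2-fold and a median of 1.27, with the assembly factor gene RRS1 at 582 against 58.0 FPKM and GNL3, a nucleolar GTPase gene, at 178 against 24.4. DNA replication genes had 11 of 30 higher past 2-fold and a median of 0.76, with the ribonucleotide reductase gene RRM1 at 258 against 79.9 FPKM and CCNE1, the cyclin E gene, at 148 against 52.9. Immediate early genes had a median of 0.76, with FOSL1 at 383 against 13.9 FPKM and MYC at 751 against 104, although FOSB stood at 0.616 against 19.3. The aryl hydrocarbon receptor and NRF2 targets had a median of 1.09 over members that went both ways, as CYP1A1, a cytochrome gene induced through the aryl hydrocarbon receptor, was at 0.258 against 11.8 FPKM and ALDH3A1 at 32.7 against 6.32. Lysosome genes were lower with a median of -0.68 and 8 of 20 past 2-fold, including the protease gene CTSL at 54.0 against 187 FPKM, while GPNMB and HEXB were higher past 2-fold. The immediate early list fell inside the random range with a pseudocount of 5.

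The 8 genes with the highest difference in the library labelled 4-OHT were IGFBP7, GSTP1, SAA2, IGLC3, KRT14, GPX1P1, CXCL3 and KRT5. GSTP1, a glutathione transferase gene, was at 2908 against 5.97 FPKM and the acute-phase gene SAA2 at 623 against 0.689. IGFBP7 (557 FPKM), the immunoglobulin light chain gene IGLC3 (289.8) and the chemokine gene CXCL3 (227) were listed at 0 in the library labelled vehicle. GPX1P1, a pseudogene of GPX1, stood at 1727 against 5.77 FPKM. It, SAA2, CXCL3 and the keratin genes have close relatives in the genome, so their reads may have been divided among copies. CDKN2A and CDKN2B, neighbouring inhibitors of cyclin-dependent kinases, were at 276 against 0.832 and 25.7 against 0.187 FPKM. The lowest were VAMP5, APOD, RASD1, PEX11A, GUSBP18 and the small RNA genes Y_RNA and U3, all listed at 0 in the library labelled 4-OHT, and OR7E14P at 0.876 against 151 FPKM. VAMP5, a membrane fusion gene, was at 144 FPKM and APOD, an apolipoprotein gene, at 96.7 in the library labelled vehicle. NDUFB3, a respiratory chain subunit gene used by most cells, was at 1.65 against 60.7 FPKM and PEX11A, a peroxisome gene, was listed at 0 against 75.7, so a value near 0 in this library may be a failed estimate.

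Further genes named by the rule fixed in advance gave these values in the libraries labelled 4-OHT and vehicle. CCND1, the cyclin D1 gene, stood at 2808 against 1296 FPKM, HPRT1 at 288 against 50.9 and GUSB at 1001 against 3165, all past 2-fold, the last 2 on the housekeeping list. ACTB was at 42273 against 21409 FPKM, GAPDH at 26042 against 18401, MKI67 at 222 against 266 and BCL2 at 10.5 against 10.7, none past 2-fold. PCSK9, which lowers LDL receptor levels, stood at 87.8 against 0.0511 FPKM on a cholesterol list that was not apart. Of the leukocyte markers 5 of 10 were measured and 4 of these were lower past 2-fold, with CD14 higher at 5.56 against 0.639 FPKM. The other lists inside the random range were mitosis (97.01 percentile), CDK inhibitors, p53 targets, fatty acid synthesis, unfolded protein response, BCL2 family, growth factor, steroid receptor, luminal, ribosomal protein, oxidative phosphorylation, hypoxia, histone and housekeeping genes. Of these, the mitosis list left the range with a pseudocount of 5 and with the GC trend removed, and the unfolded protein response list with the GC trend removed.

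**Figure D3:**
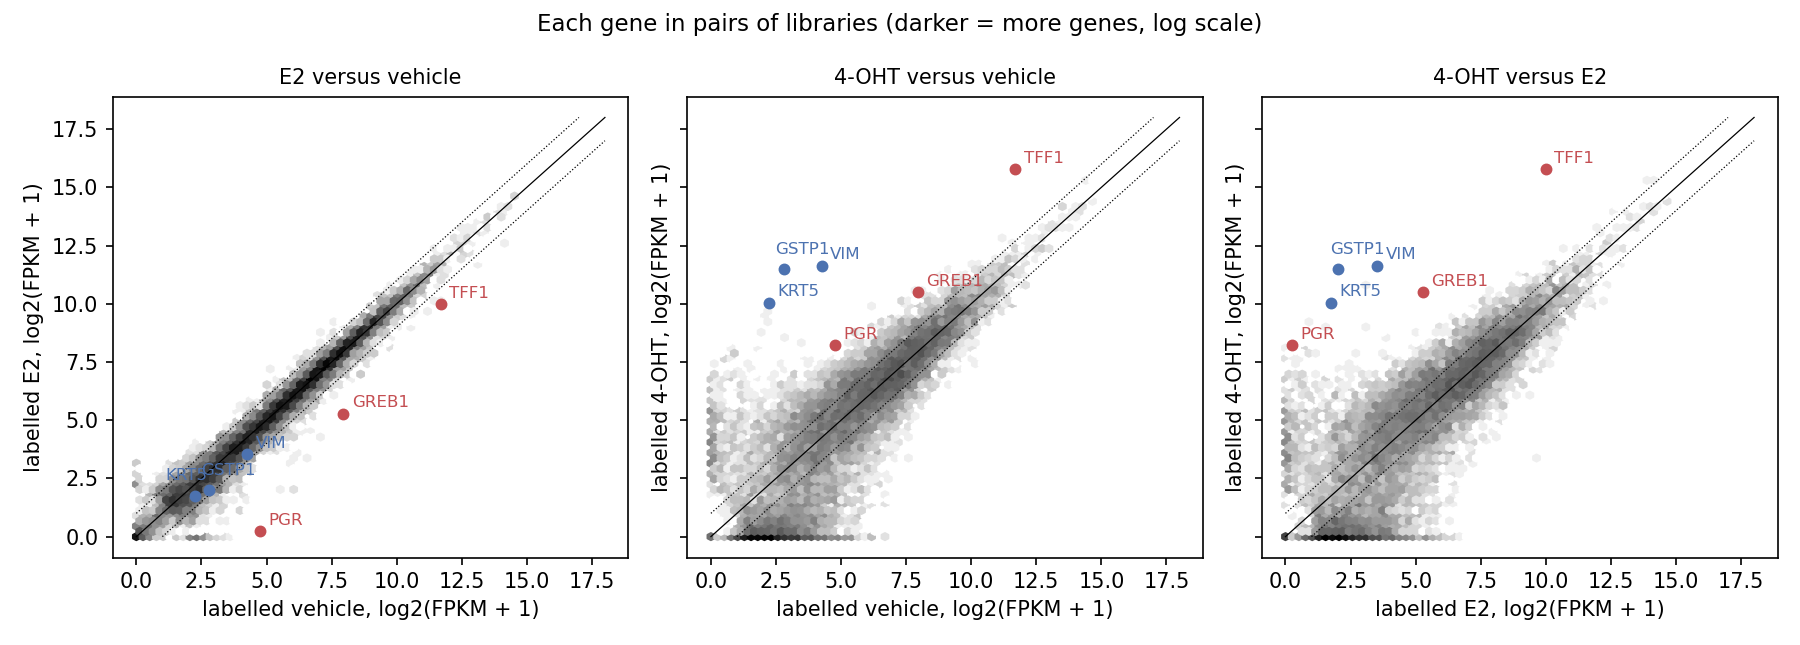
Each gene by its log2(FPKM + 1) in pairs of libraries, with darker cells for more genes on a log scale, a solid line of equality and dotted lines at 2-fold. The libraries labelled vehicle and E2 lie close to the line (7.39% of 15549 genes past 2-fold), and either pair with the library labelled 4-OHT is wide (50.6% and 52.8%); marked are PGR, TFF1 and GREB1 in red and KRT5, VIM and GSTP1 in blue.

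The third comparison set the library labelled 4-OHT against the library labelled E2, the pair that contrasts the 2 receptor ligands by their labels. Estrogen-induced genes were higher in the library labelled 4-OHT: 28 of 34 passed 2-fold, 0 were lower past 2-fold, and the median was 2.09. PGR stood at 300.0 against 0.185 FPKM, TFF1 at 55769.7 against 1020.4 and GREB1 at 1439 against 37.9. Estrogen-repressed genes were lower, with 10 of 16 past 2-fold and a median of -2.35, including PSCA at 9.53 against 381 FPKM and TGFB3 at 13.5 against 583. Basal and mesenchymal markers were also higher, with medians of 4.41 and 3.26, and 7 of 9 and 9 of 11 members past 2-fold. Of 15549 genes, 3434 were at least 2-fold higher and 4772 at least 2-fold lower, or 52.8%, but 2972 and 2973 with a pseudocount of 5 and 3085 and 3011 with a mean of at least 5 FPKM, so which direction holds more genes depends on these settings. The column headers call this pair E2 and vehicle.

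Cell division genes were higher in the library labelled 4-OHT than in the library labelled E2. DNA replication genes had 22 of 30 past 2-fold and a median of 1.48, with RRM2 at 579 against 96.8 FPKM and the origin recognition gene ORC1 at 139 against 25.7. Mitotic genes had 20 of 31 past 2-fold and a median of 1.51, with the cyclin gene CCNA2 at 356 against 60.4 FPKM and the kinesin gene KIF11 at 92.5 against 17.9. Ribosome biogenesis genes had 14 of 18 past 2-fold and a median of 1.46, including the pseudouridine synthase gene DKC1 at 561 against 88.8 FPKM. Interferon response genes had a median of 1.70 and 18 of 24 past 2-fold, including MX2 at 69.3 against 0.807 FPKM. Cholesterol genes had a median of 0.63, with HSD17B7 at 97.3 against 14.4 FPKM and TM7SF2, another enzyme gene of that pathway, at 452 against 1717. Growth factor genes had a median of 0.92 over 9 members higher and 6 lower past 2-fold. The ligand genes AREG, at 34.3 against 1.34 FPKM, and NRG1, at 16.8 against 0.0678, were among the higher ones, and the receptor gene ERBB4, at 0.152 against 11.5, among the lower. Lysosome genes had a median of -0.65 with 7 of 20 lower past 2-fold.

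The genes with the highest difference between the libraries labelled 4-OHT and E2 were CXCL1, GSTP1, SAA2, IGFBP3, IGFBP7, the complement gene C3, SAA1 and KRT5. CXCL1 was at 785 FPKM and SAA2 at 623, both listed at 0 in the library labelled E2. IGFBP3 stood at 672 against 0.774 FPKM, C3 at 748 against 1.23 and SAA1 at 585 against 0.774. The lowest were VAMP5, APOD, APOBEC3A, C2orf72, UPK1A and GUSBP18, all listed at 0, ZNF423 at 0.0957 against 134 FPKM and CCDC183 at 0.371 against 157. MYC stood at 751 against 45.4 FPKM, CDKN1A, the p21 gene, at 526 against 1447, and ESR1 at 290.3 against 693, all past 2-fold. The remaining 15 lists lay inside the random range, among them the luminal markers with a median of -0.39 and the leukocyte markers with 4 of 5 lower past 2-fold. Of these, the aryl hydrocarbon receptor and NRF2 targets left it with a pseudocount of 5 and with no filter, and the histone list with the GC trend removed.

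The differences of the libraries labelled E2 and 4-OHT from the library labelled vehicle were also set side by side, which shares that library between them. Both were lower past 2-fold for 412 genes, against 231 for independent lists and 31.4 for simulated unchanged libraries, and both were higher for 75, against 78.7 and 31.4. Of the 748 genes lower in the library labelled E2, 209 were listed at 0 in the library labelled 4-OHT. All 209 count as lower in both, and such values may be failed estimates, so the excess over 231 may rest partly on them. Both were lower for 164 genes with a pseudocount of 5 and for 180 with a mean of at least 5 FPKM. Among the genes lower in the library labelled E2, 99 were higher in the library labelled 4-OHT, against 147 for independent lists and 0.11 simulated, and 160 went the reverse way, against 124 and 0.09. The simulated libraries hold no real differences. In both comparisons they have a spread taken from the median absolute deviation of the pair labelled vehicle and E2, which gives little weight to its large differences. Their counts therefore had to be lower, and an excess over them shows no agreement. SERPINA1 and CITED1 were lower in both, while PGR, GREB1, TFF1 and MYC were lower in the library labelled E2 and higher in that labelled 4-OHT. The correlation across genes was 0.075, which cannot be set against the 0.50 of the simulated libraries for the same reason. The covariance was 0.081 against 0.078 simulated. The simulated value is set by the spread fed in, which counts real differences of that pair as noise. The near match therefore cannot show what the shared library alone gives. Genes are not independent replicates, and part of any excess may come from the shared library, which cannot be divided.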

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

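No paired analysis was possible because each group holds 1 library. With the library names kept, no list called apart reversed under the other pseudocounts, filters, scalings, row choice and GC correction: of 647 list results 628 kept their side of the threshold, 11 passed it anew and 8 lost it. Named genes were rerun only with a pseudocount of 0.1 and the 2 other scalings, where 1085 of 1107 results kept their side, 17 passed it anew and 5 lost it, and none past 2-fold reversed. Upper-quartile scaling moved the median of all genes by -0.12 between the libraries labelled 4-OHT and vehicle.

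For the libraries labelled E2 and vehicle, the 1149 genes past 2-fold became 485 with a pseudocount of 5 and 696 with a mean of at least 5 FPKM, 3080 at 1.5-fold and 386 at 3-fold. With a mean of at least 5 FPKM the libraries labelled 4-OHT and vehicle gave 2724 genes higher and 2967 lower. At 3-fold they gave 5090 genes and those labelled 4-OHT and E2 gave 5305. Genes differing in the same direction from the library labelled vehicle went from 487 to 182 with a pseudocount of 5, 243 with a mean of at least 5 FPKM, 1267 at 1.5-fold and 183 at 3-fold.

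The following were chosen after seeing the data. The 12886 protein-coding genes alone gave 711, 5965 and 6338 genes in the order of the comparisons, with fewer genes counted. Names from the column headers gave 8206 genes for E2 against vehicle and 1149 for 4-OHT against vehicle, because they rename the pairs. E2 against vehicle then becomes the pair labelled 4-OHT and E2, where the median of the estrogen-induced list is 2.09 instead of -1.28, and TFF1 and PGR turn with it. They also gave 4 check genes highest in the library then named E2, against 0. The difference between the libraries labelled E2 and vehicle followed GC content across 9085 genes (Spearman 0.24, genes not being independent), and removing that trend ended no call of a list and added 5 over the 3 comparisons.

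Of named genes at 5 to 20 FPKM in both other libraries, 5.75% were listed at 0 in the library labelled 4-OHT, against 0% in each of the others. This count and the tests of genes listed at 0 were first made on all identifiers and limited to named genes after their results were seen.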

Other observations

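The genes of this paragraph and the next were chosen after their values were seen, apart from those on the fixed lists. Of 9 measured chemokine genes, 7 were higher past 2-fold in the library labelled 4-OHT than in the library labelled vehicle, with a median of 5.37, and 0 were lower. Of 12886 protein-coding genes, 2705 were higher and 3260 lower in that pair. Measured genes needed a mean of at least 1 FPKM over the 3 libraries. Some, such as CXCL5 and CXCL6, therefore entered only through high values in the library labelled 4-OHT, which partly sets this count. The neutrophil-attracting chemokine gene CXCL1 was at 785 against 3.25 FPKM and CXCL17 at 92.5 against 1.27, while CXCL5 (52.9 FPKM) and CXCL6 (51.2) were listed at 0 in both other libraries. LCN2, which encodes an iron-siderophore binding protein, stood at 2098 against 8.51 FPKM, and the calprotectin subunit gene S100A9 at 1134 against 26.8, although the 14 S100 genes went both ways, with 5 higher and 4 lower past 2-fold, as did the 14 serpin genes, also with 5 and 4. Among 6 genes of insulin-like growth factor binding proteins, 3 were higher past 2-fold in the library labelled 4-OHT than in that labelled vehicle. In contrast 3 were lower past 2-fold in the library labelled E2, including IGFBP4.

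Of 25 measured keratin genes, 11 were higher and 5 lower past 2-fold in the library labelled 4-OHT than in that labelled vehicle. KRT7 was at 3188 against 54.4 FPKM, KRT16 at 292 against 10.2 and KRT81 at 1382 against 40.8, whereas KRT8 and KRT18 stood at 36641 against 25765 and 18095 against 11477, neither past 2-fold. KRT13 was at 106 FPKM in the library labelled vehicle, 3.95 in that labelled E2 and 33.2 in that labelled 4-OHT. Of 389 zinc finger genes with ZNF symbols, 153 were lower and 50 higher past 2-fold in the library labelled 4-OHT than in that labelled vehicle. Over all 12886 protein-coding genes, 3260 were lower and 2705 higher in that pair. The most weakly expressed of 10 bins of protein-coding genes had a median of -1.34 there, so the ZNF counts may reflect low expression. In the library labelled E2, 3 of the 389 ZNF genes were lower and 0 higher than in that labelled vehicle, against 484 and 227 of the 12886 protein-coding genes.

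Of the tests that follow, only the count of check genes highest in the library headed E2 was chosen before its result was seen. The estrogen-induced check genes went against the labels: 6 of 6 were lowest in the library labelled E2, which argues against labels that name the right libraries if these genes respond to estrogen as is generally known. A candidate explanation is a mislabelled sample: each file is attached to the wrong sample and its column header names the right one. This asked for at least 5 of 6 check genes highest in the library headed E2. The count was 4, between the bounds set for and against it, with MYB and PDZK1 highest elsewhere. PDZK1 was near the floor, at 2.22 FPKM in the library labelled vehicle and 0.992 in that labelled 4-OHT. Its order, and with it the miss of the bound, is therefore uncertain. The fixed lists went in the direction of the headers for E2 and vehicle, although the estrogen-induced list includes the 6 check genes. Of its 34 genes, 24 were highest in the library headed E2 and 31 lowest in the library headed vehicle. Of 16 estrogen-repressed genes, 13 were lowest in the library headed E2 and 13 highest in the library headed vehicle. By the headers, however, 23 of the 34 estrogen-induced genes were at least 2-fold higher with 4-OHT than with vehicle, and 0 lower. An exchange of only the labels E2 and 4-OHT would also put the 24 genes highest with E2, and the 31 lowest with 4-OHT. The naming by headers therefore cannot be told apart from other exchanges. Each treatment has 1 library, and the library headed E2 also differs in markers of cell type.

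In the library labelled 4-OHT, 72 named genes were at 50 FPKM or more and under 1 FPKM in both others, among them PLS3 (303 FPKM), MSN (282), NNMT (234), CHI3L1 (282) and ETS1 (53.3). The authors' normalization by 1 factor per library is argued against as the whole cause, since such a factor moves every gene alike, and the median difference of all genes was at most -0.157 against either other library. RNA of other cells may contribute: the basal and mesenchymal lists, which hold 0 of the 72 genes, had medians of at least 3.26 against both other libraries, led by VIM (3179 FPKM) and KRT5 (1060.3), although 7 of 9 and 8 of 11 measured members were also at 1 FPKM or more in both others. A response of the cells to 4-OHT alone cannot be told apart from that, because the treatment has 1 library. Another cell stock, batch or processing of this library, which correlated at 0.929 and 0.925 with the others while they correlated at 0.990, was not tested and stays open for every difference of this library. CDKN2A, a gene generally reported as deleted in MCF-7, was at 276 FPKM, but its deletion in these cells was not examined.

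The reverse also held, as 37 of 8320 named genes at 20 FPKM or more in both other libraries were listed at 0 in the library labelled 4-OHT, against 1 and 0 genes for the libraries labelled E2 and vehicle. VAMP5 and APOD were the 2 with the highest values among named ones. The tests of this paragraph first used all identifiers and were limited to named genes after their results were seen, because only 40 of the 68 identifiers listed at 0 (58.8%, under the 80% asked for) had a known length, which made those results void. Lower depth is argued against, since the 37 named genes, all with a known length, would be expected at a median of 274 reads and at least 10.0. These expected reads use the longest transcripts and can be too high. Choosing genes at 20 FPKM or more nearly set this result, so it is a calculation more than a test. Loss of low-copy transcripts could also give zeros, and their share did fall from 5.75% of genes at 5 to 20 FPKM to 0.081% at 50 FPKM or more, but silencing of weakly expressed genes, in response to treatment or in another cell population, would give the same and cannot be told apart. Estimates that failed were not tested.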
